A study of Mus musculus with 8 samples.

How the data were processed

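Polyadenylated RNA was measured in 8 libraries of mouse E14 embryonic stem cells, 2 for each of 4 genotypes. The authors deposited a table of counts per gene, and per the labels the libraries came from an Illumina TruSeq kit with a reverse-stranded protocol. Per the submitters' processing notes the reads were aligned with STAR 2.4.2a to mouse genome build mm10 (GRCm38). The counting tool, whether it used strand, and the annotation release are not given in the sources used here. The values were whole numbers, and the number of count columns left unused was 0. Total counts per library lay between 13229771 and 26333907. Sequencing reads were not analysed here.

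Gene identifiers were matched without their version suffix to symbols and to GENCODE M21 (GRCm38). Of 47643 genes, 47224 matched a symbol and 39106 had the same version. Genes were filtered with filterByExpr by genotype, which left 16388, and scaled with TMM factors. One mean per genotype was fitted to all 8 libraries in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with robust dispersion and robust quasi-likelihood estimates. Each comparison was tested with edgeR's quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) taken from the same test. CPM were taken from TMM-scaled library sizes.

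The genotypes, the 5 comparisons, the tests, the gene lists, the seed families and the rule for naming genes were chosen before the data were examined. The 5 comparisons were each KO against WT, Drosha KO against Dgcr8 KO, and Ago1_2 KO against the mean of the other KO groups. Named genes were the 4 targeted genes, and for each KO against WT the 10 largest changes in each direction among called genes. These needed a mean of 5 CPM or more in 1 group, both KO libraries on the same side of both WT libraries, and a symbol that is not of a predicted gene. The rule took 5 in each direction for the comparisons among KOs, 10 in each direction for genes called in all 3 KOs by their smallest change, and up to 4 members of each list by p-value.

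Of 38 gene lists, 36 had the 5 measured members needed for a test. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted by the per-gene call over all genes and with p-values adjusted over the list alone. Seed sites of 13 miRNA families were sought in the longest annotated 3′ UTR of 50 bases or more. For each hexamer, log2 fold change was regressed on its presence, with log2 UTR length and UTR GC content as covariates. Each family's 6-base seed site was ranked among all 4096 hexamers by t, the slope over its SE. The plan made beforehand named the slope itself. Chromosome medians were compared with 10000 random gene sets of the same size, and with fewer sets for the GC offset. Correlations and covariances between comparisons were set beside 20 simulations of unchanged genotypes that share the WT libraries.

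A gene without counts in a group was given a floor of 3 counts over the group, and its fold change is then a bound. Where a group held 1 to 3 counts, the ratio is given with an exact 95% binomial interval. Intervals and floors cover counting error only. The steps were tested on simulated data over 15426 genes: in a simulated Drosha KO against WT, 24.2% of genes changed 2-fold and 83.8% of those changed 4-fold were recovered, with 6 false calls.

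The alternatives were DESeq2 size factors, library size only, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM, only the groups compared, the replicate number as a block, a 2-fold limit and each library left out in turn. An offset for transcript GC content was added after the data were seen. Computations outside R used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.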

Results

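RNA was sequenced from E14 mouse embryonic stem cells of the 129/Ola background grown in 2i medium, which blocks the MEK and GSK3 kinases and holds the cells in a naive state. Cells were wild type (WT) or labelled as knockouts (KO) of Dgcr8, of Drosha, or of Ago1 and Ago2 together (Ago1_2 KO), with 2 libraries each. DROSHA and DGCR8 form the Microprocessor, which cuts primary miRNA transcripts in the nucleus, and Argonaute proteins carry mature miRNAs to their targets. Total counts were 17783035 and 22299884 in WT, 18361044 and 15575868 in Dgcr8 KO, 17589425 and 26333907 in Drosha KO, and 24172661 and 13229771 in Ago1_2 KO. The labels do not say whether the libraries of a genotype came from separate cultures or clones, so p-values measure the spread between these samples. Between the libraries of 1 genotype, 2427 genes differed by over 2-fold in WT, 2250 in Drosha KO, 707 in Ago1_2 KO and 580 in Dgcr8 KO. The first principal components held 44.8%, 25.1% and 10.6% of the variance.

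The targeted genes were read first. Drosha mRNA (ENSMUSG00000022191.15, GRCm38 chromosome 15, 12824815 to 12935291) fell in Drosha KO to 24.6% of WT, a log2 change of -2.02 ± 0.24 (SE, edgeR adjusted p 0.00196), with 51.2 and 82.4 CPM against 278 and 266 in WT. Dgcr8 mRNA (ENSMUSG00000022718.11, chromosome 16, 18253948 to 18289246) rose 5.13-fold in the libraries labelled Dgcr8 KO, to 392 and 370 CPM from 78.1 and 70.5 in WT (adjusted p 0.00101). It also rose 3.62-fold in Drosha KO (adjusted p 0.00132) and was not called in Ago1_2 KO (1.17-fold, adjusted p 0.426). Dgcr8 mRNA carries hairpins that the Microprocessor itself cuts. In the libraries labelled Ago1_2 KO, Ago2 (ENSMUSG00000036698.10, chromosome 15, 73095844 to 73184935) stood at 59.5% of WT without being called (adjusted p 0.132), at 216 and 195 CPM against 464 and 227. Without WT 2, the WT library nearer to Ago1_2 KO, the log2 change of Ago2 was -1.15, a fit that rests on WT 1 alone. Other libraries left out in turn gave smaller falls of Ago2 in Ago1_2 KO. Ago1 (ENSMUSG00000041530.16, chromosome 4, 126435012 to 126468583) did not fall there: it stood at 147% of WT (adjusted p 0.301). Both rose in Drosha KO, Ago1 by 1.46 ± 0.37 and Ago2 by 1.44 ± 0.33 on the log2 scale (adjusted p 0.0332 and 0.0235). Against the mean of Dgcr8 and Drosha KO, Ago2 was called lower in Ago1_2 KO (-1.67 ± 0.3, edgeR adjusted p 0.0121). Ago1 was not called there (-0.68 ± 0.32, adjusted p 0.283). Counts per gene do not read an edit that leaves the mRNA in place, so the labels of Dgcr8 KO and Ago1_2 KO were not checked by the level of their own mRNA.

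**Figure D1:**
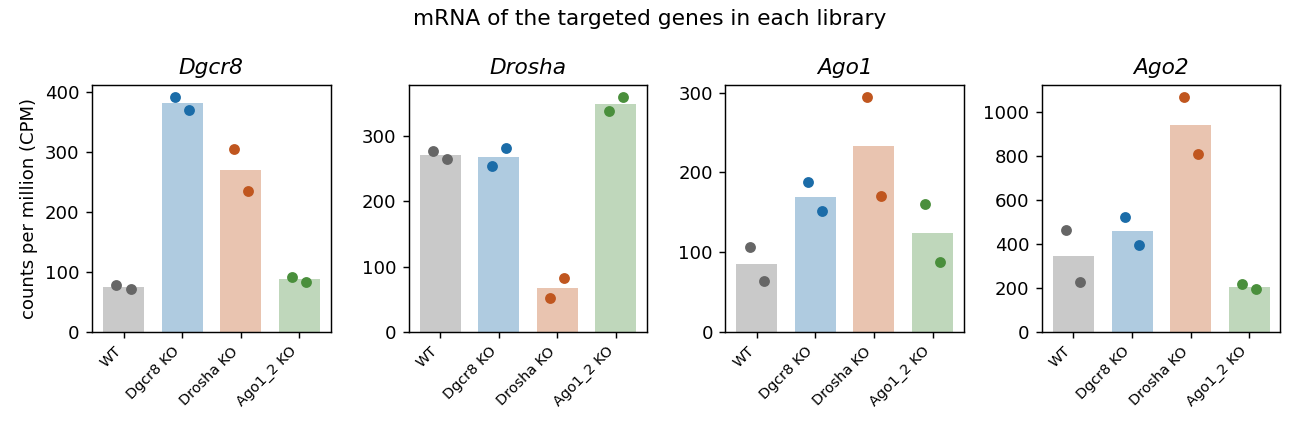
CPM of Dgcr8, Drosha, Ago1 and Ago2 in each library. Points are libraries and bars are means of 2; Drosha mRNA was lowest in Drosha KO, and Dgcr8 mRNA was highest in the libraries labelled Dgcr8 KO.

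The Mir1306 gene lies inside a coding part of Dgcr8 exon 2 (chromosome 16, 18284239 to 18284317). It had 0 counts in both libraries labelled Dgcr8 KO, 36 and 14 in WT, 170 and 246 in Drosha KO and 61 and 35 in Ago1_2 KO. Against the floor of 3 counts over the group it was at least 15.7-fold lower in Dgcr8 KO than in WT and at least 111-fold lower than in Drosha KO. Counts of genes that overlap depend on how reads were assigned, which is not given in the sources used here.

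The libraries labelled Dgcr8 KO were set against WT to ask what changes when the Microprocessor loses its RNA-binding subunit. Primary miRNA transcripts rose: Mir17hg, host of the miR-17-92 cluster, by 2.72 ± 0.33 on the log2 scale (SE, 2 libraries per group, edgeR adjusted p 0.0045), and the miR-290 cluster genes Mir291a, Mir291b and Mir293 by 3.06 ± 0.34, 2.42 ± 0.32 and 2.20 ± 0.31. Genes of the ATF4 response to amino acid shortage fell, Ddit4 by 2.91 ± 0.22 and Chac1 by 4.14 ± 0.45 (adjusted p 0.000567 and 0.0026). The imprinted genes Plagl1 and Peg10 rose by 4.16 ± 0.24 and 4.22 ± 0.45 (adjusted p 0.000116 and 0.00258). Of 7 listed Y-linked genes, the 4 that passed the low-count filter were without counts in both Dgcr8 KO libraries, which puts Eif2s3y at least 865-fold, Ddx3y at least 361-fold, Uty at least 199-fold and Zfy1 at least 29.9-fold lower than WT. Uba1y, also on the Y short arm, had 1 count against 398, a 360-fold difference (95% interval 64.2 to 14200), while all annotated chromosome Y genes together held 1830 and 1602 counts in these libraries and 4606 and 6438 in WT.

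In this comparison 1136 genes were called, 401 higher and 735 lower, and 4916 had an unadjusted p under 0.05. Among the largest rises were the acetyltransferase genes Nat8f3 (340-fold, 95% interval 60.5 to 13500) and Nat8f7 (119-fold, 32.5 to 989), near-identical relatives between which reads may be split. Btla, Kis2, Nespas, Mep1b and Akap6 rose by 3.63 to 4.36. Nespas runs antisense to Gnas, so its counts are uncertain without the counting strand. Among the largest falls, Creb5 was 272-fold lower (48.4 to 10800) and Phlda2 285-fold lower (50.7 to 11300), while P2rx3, Inhbe, Adssl1 and Atp2b2 changed by -6.02 to -5.10. The count was 40 without Dgcr8 KO 1, 60 without Dgcr8 KO 2, 4245 without WT 1 and 524 without WT 2. It was 2032 without Drosha KO 1, 2007 without Drosha KO 2, 465 without Ago1_2 KO 1 and 462 without Ago1_2 KO 2. Of the 20 largest changes, 10 kept their call without Dgcr8 KO 1, 11 without Dgcr8 KO 2 and 18 without WT 2, and none changed sign. Of the 12 with over 3 counts in both groups, the fold moved by over 1.5-fold for 2 without Dgcr8 KO 1, 1 without Dgcr8 KO 2, 5 without WT 1 and 3 without WT 2. P2rx3 had 47.7 and 8.61 CPM in WT 1 and WT 2 and changed by -4.30 without WT 1, and Creb5 had 13.5 and 3 CPM.

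Of 36 gene lists, 13 were called by camera in Dgcr8 KO, 8 higher and 5 lower. None held after adjustment with an estimated correlation, where 4 had an unadjusted p under 0.05. Among 19 miRNA host transcripts 8 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p 2.57e-06, p = 0.0116 with an estimated correlation). Among 166 annotated miRNA genes 29 rose and 4 fell (48 and 8 adjusted over the list alone; 7.71e-06, p = 0.00257 with an estimated correlation). The medians were 1.90 and 0.55, or 1.88 and 0.54 with genes at 0 set to their bound. Annotated miRNA genes can lie within the same cluster, as Mir23b, Mir27b and Mir24-1 do on chromosome 13, and host transcripts hold miRNA genes. Counts of such members, here and in the other comparisons, are not independent of each other or between the 2 lists. Of 24 genes of the unfolded protein and amino acid stress responses, 11 fell and 1 rose (16 and 1 adjusted over the list alone; 9.81e-07, p = 0.00551 with an estimated correlation). Of 38 imprinted genes, 10 rose and 5 fell (14 and 6 adjusted over the list alone; 0.0153, p = 0.0277 with an estimated correlation), a call that ended without WT 1 (0.0732). Without Dgcr8 KO 1 or Dgcr8 KO 2, 2 and 3 host transcripts, 7 and 10 annotated miRNA genes and 4 and 4 imprinted genes rose, and 3 and 3 stress genes and 0 and 1 imprinted genes fell. Without WT 2, 16 annotated miRNA genes rose and 3 imprinted genes fell.

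Two-cell-like genes, which mark the rare cells that resemble the embryo at its first cleavage, also rose in Dgcr8 KO. Of 26 measured, 9 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 2.10 and a camera adjusted p of 1.43e-09 (p = 0.124 with an estimated correlation). The number was 0 without Dgcr8 KO 1, 0 without Dgcr8 KO 2 and 2 without WT 2. Most members belong to families of near-identical copies, so counts of single members are uncertain. Of 24 glycolysis genes 9 fell and 0 rose, among them Aldoc (-1.94 ± 0.27), Slc16a3 and Slc2a1 (16 fell adjusted over the list alone; camera 9.87e-06, p = 0.0667 with an estimated correlation). The number that fell was 2 with the GC offset, 0 without Dgcr8 KO 1, 1 without Dgcr8 KO 2, 15 without WT 1 and 4 without WT 2. Fold changes in Dgcr8 KO followed transcript GC content across 16315 genes (Spearman -0.44; genes are not independent replicates), against 0.0055 in Drosha KO and -0.044 in Ago1_2 KO, and 0.43 in Drosha KO against Dgcr8 KO and 0.25 in Ago1_2 KO against the mean of the others.

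Of 22 formative and primed pluripotency genes, which mark exit from the naive state, 5 rose and 1 fell in Dgcr8 KO (7 and 2 adjusted over the list alone; camera 0.0242, p = 0.283 with an estimated correlation). Zic2 rose by 2.09 ± 0.26 and Utf1 fell by 1.81 ± 0.32, and the list's call ended without WT 1 (0.188) and without Dgcr8 KO 2 (0.0667). Of 20 Wnt targets 2 rose, Lef1 and Axin2 (6 adjusted over the list alone; 0.00439, p = 0.0836 with an estimated correlation; 0.158 without WT 1). Hox genes were called with 0 of 23 rising (0.0242, p = 0.461 with an estimated correlation; 0.513 without WT 1 and 0.13 without Dgcr8 KO 2). Of 25 genes of the miRNA machinery 2 rose, Dgcr8 and Lin28a, and Mov10 fell (0.0261, p = 0.267 with an estimated correlation; 0.257 without WT 2 and 0.0582 without Dgcr8 KO 1). Without Dgcr8 KO 1, Dgcr8 KO 2 and WT 2, 1, 1 and 2 formative genes, 0, 0 and 1 Wnt targets and 1, 1 and 1 machinery genes rose, against 12 machinery genes without WT 1. The list of lysosome and autophagy genes was called lower with 1 of 27 falling (0.0242, p = 0.46 with an estimated correlation; 0.201 without WT 2, 0.0542 without Dgcr8 KO 1), and 5 fell without WT 1 and 0 without WT 2, Dgcr8 KO 1 or Dgcr8 KO 2.

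Drosha KO was set against WT to ask the same of the catalytic subunit. Primary miRNA genes rose in Drosha KO, Mir291a by 4.29 ± 0.35 and Mir290a by 3.80 ± 0.38 on the log2 scale (SE, 2 libraries per group, edgeR adjusted p 0.000649 and 0.00103). Mir23b and Mir29a, at 0 counts in WT, were at least 72.6-fold and at least 69.3-fold higher. Two-cell-like genes rose, Zscan4b and Zscan4e among the 23 called of 26, as did the miR-290 family target Lats2, a Hippo pathway kinase, by 2.56 ± 0.41. The mesoderm gene T (Brachyury) fell by 7.06 ± 0.73 and the pluripotency RNA-binding gene Lin28a by 5.41 ± 0.52, from 22.9 and 22.8 CPM to 0.190 and 0.579. In Dgcr8 KO, Lin28a rose by 1.51 ± 0.39 to 65.2 CPM, and T, at 56.4 CPM, was not called (adjusted p 0.107).

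In Drosha KO 1862 genes were called, 1071 higher and 791 lower, and 4908 had an unadjusted p under 0.05. Other large rises were Tmem132d (220-fold, 95% interval 39.2 to 8730), Mir27b (111-fold, 37.7 to 541), Mir24-1, Mir19b-1, Mir18b and Kis2. Other large falls were P2rx3, Ptprtos, Htr5a, B4galnt2, Calca, Slc7a11, Sp5 and Inhbe, at -5.95 to -4.15. Ptprtos is an antisense transcript, uncertain without the counting strand. The count was 714 without Drosha KO 1, 2465 without Drosha KO 2, 4003 without WT 1, 1194 without WT 2, 1027 without Dgcr8 KO 1, 1020 without Dgcr8 KO 2, 1066 without Ago1_2 KO 1 and 1070 without Ago1_2 KO 2. Of the 20 largest changes, 19 kept their call without Drosha KO 1 and 20 without any other single library. Of the 16 with over 3 counts in both groups, the fold moved by over 1.5-fold for 4 without Drosha KO 1, 6 without Drosha KO 2, 7 without WT 1 and 8 without WT 2. Slc7a11 had 21.3 and 4.45 CPM in WT 1 and WT 2, and without WT 1 it changed by -3.17 and P2rx3 by -4.23.

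Of 36 gene lists, 14 were called in Drosha KO, 8 higher and 6 lower. Annotated miRNA genes were the 1 list that held with an estimated correlation (42 rose and 0 fell; 48 and 0 adjusted over the list alone; camera 8.88e-09, p = 0.00103 with an estimated correlation), and their median was 0.76. Among host transcripts 9 rose and 1 fell (11 and 2 adjusted over the list alone; camera 0.000543, p = 0.0284 with an estimated correlation; 0.0518 without Drosha KO 2, where 10 rose and 5 fell). Of 26 two-cell-like genes 23 rose (26 adjusted over the list alone; 2.58e-21, p = 0.0441 with an estimated correlation), with a median of 3.99; the number was 15 without WT 2. Amino acid stress genes fell as in Dgcr8 KO, with 13 of 24 lower and 1 higher (14 and 2 adjusted over the list alone; 3.53e-07, p = 0.00487 with an estimated correlation) and Ddit4 at -3.08 ± 0.22; 7 fell without Drosha KO 1. Of 36 interferon and RNA sensing genes 9 rose and 0 fell (14 and 0 adjusted over the list alone; 7.57e-06, p = 0.0836 with an estimated correlation). These included Mavs (1.23 ± 0.19), Oasl1, Rsad2 and Oas2; 1 rose without Drosha KO 1 and 14 without Drosha KO 2.

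Of 22 reported miR-290 family targets Lats2, Lefty1, Fndc3a and Tgfbr2 rose and Txnip fell (4 and 1; 9 and 1 adjusted over the list alone; camera 0.00441, p = 0.112 with an estimated correlation). Of 41 extracellular matrix and adhesion genes 11 rose and 2 fell (13 and 3 adjusted over the list alone; 0.0043, p = 0.0489 with an estimated correlation), led by the integrin Itga5 (1.74 ± 0.19). Of 22 formative genes 6 rose and 1 fell (9 and 1; 0.000764, p = 0.153 with an estimated correlation). Wnt targets fell, with 5 lower and 2 higher of 20 (0.022, p = 0.136 with an estimated correlation), among them T, Sp5 and Axin2; the call ended without WT 2 (0.0917) and without Drosha KO 2 (0.137). Of 39 germline genes 5 fell, led by Xlr3a (0.0193, p = 0.226 with an estimated correlation; 0.139 without WT 1). Of 18 DNA methylation genes Dnmt3a alone was called, rising by 1.32 ± 0.26 (list 0.027, p = 0.109 with an estimated correlation; 0.0977 without WT 2, 0.144 without Drosha KO 1). Of 30 DNA replication and mitosis genes 3 fell, Ccnb2, Mcm6 and Gins2 (0.0303, p = 0.193 with an estimated correlation; 0.0877 without WT 1, 0.382 without Drosha KO 2).

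Left-out libraries moved these counts in Drosha KO. Without Drosha KO 1, 5 extracellular matrix, 2 formative and 0 DNA methylation genes rose, and 3 germline and 1 DNA replication genes fell. Without Drosha KO 2, 11 formative and 3 DNA methylation genes rose and 1 DNA replication gene fell. Without WT 1, 6 DNA methylation genes rose and 7 DNA replication genes fell, and without WT 2, 4 extracellular matrix genes rose. The DNA methylation and formative lists share Dnmt3a, the enzyme that sets new methylation as cells leave the naive state.

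Ago1_2 KO was set against WT to ask what changes when miRNAs lose their main effectors. All 26 two-cell-like genes rose, with a median of 6.02; Zscan4f rose by 7.25 ± 0.46 and Zscan4c by 7.29 ± 0.56 on the log2 scale (SE, 2 libraries per group, edgeR adjusted p 0.000177 and 0.000274). Lefty1, an inhibitor of Nodal signalling and a reported miR-290 family target, rose by 5.32 ± 0.84, and Nodal itself by 1.66 ± 0.26. The neural transcription factor gene Pax6 rose by 5.60 ± 0.53, from 0.210 to 10.4 CPM. T was 910-fold lower (1 count against 908, 95% interval 163 to 36000), and Lin28a fell by 4.24 ± 0.47. T differed between the WT libraries, with a mean of 22.9 CPM and an SD of 15, which that interval does not cover. Annotated miRNA genes did not shift: 5 rose and 2 fell of 166, with a median of 0.00 (camera adjusted p 0.769), and 1 of 19 host transcripts rose and 2 fell (0.925).

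In Ago1_2 KO 2887 genes were called, 1677 higher and 1210 lower, and 5706 had an unadjusted p under 0.05. Other large rises were BC080695 (at least 100-fold), Tmem132d (284-fold, 95% interval 50.6 to 11300), Rdh1 (219-fold, 39.0 to 8710), Inpp4b (195-fold, 34.7 to 7760) and AF067061 (162-fold, 44.5 to 1340). Other large falls were Htr5a, Ubap1l, P2rx3, S1pr3, Cyp2b23, Pou2f3, Cldn7 and Angptl6, at -5.82 to -3.40. The count was 692 without Ago1_2 KO 1, 556 without Ago1_2 KO 2, 4955 without WT 1, 1697 without WT 2, 1696 without Dgcr8 KO 1 and 1684 without Dgcr8 KO 2. Of the 20 largest changes, 17 kept their call without Ago1_2 KO 1, 16 without Ago1_2 KO 2 and 20 without any other single library. Of the 14 with over 3 counts in both groups, the fold moved by over 1.5-fold for 2 without Ago1_2 KO 1, 6 without Ago1_2 KO 2, 7 without WT 1, among them P2rx3 (-2.53), and 5 without WT 2.

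Of 36 gene lists, 12 were called in Ago1_2 KO, 8 higher and 4 lower, and none held after adjustment with an estimated correlation. The two-cell-like call had a camera adjusted p of 1.66e-28 (p = 0.0284 with an estimated correlation), with 26 of 26 higher adjusted over the list alone. Of 22 miR-290 family targets 9 rose and 1 fell (11 and 1 adjusted over the list alone; 0.000295, p = 0.0631 with an estimated correlation), among them Pbx3, Tgfbr2 and Fndc3a; 3 rose without Ago1_2 KO 1 and 1 without Ago1_2 KO 2. Of 36 interferon genes 13 rose (19 adjusted over the list alone; 1.43e-06, p = 0.0695 with an estimated correlation), including Mavs, Oasl1, Zbp1 and Oas2; 4 rose without Ago1_2 KO 1 and 4 without Ago1_2 KO 2. Of 21 Nodal, TGF-beta and BMP targets 8 rose and 1 fell (0.00487, p = 0.154 with an estimated correlation; 0.0961 without WT 1). Of 15 neuroectoderm genes 6 rose, led by Pax6, Zfp521, Tubb3 and Ncam1 (0.00933, p = 0.0334 with an estimated correlation; 0.0908 without WT 1). Stress genes fell again, 13 lower and 3 higher of 24 (0.00036, p = 0.0151 with an estimated correlation); 7 fell without Ago1_2 KO 1 and 6 without Ago1_2 KO 2. Without Ago1_2 KO 1, 4 Nodal, TGF-beta and BMP targets and 3 neuroectoderm genes rose, and without Ago1_2 KO 2, 2 of those targets.

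Of 12 fibroblast genes 6 rose in Ago1_2 KO (camera 0.00254, p = 0.0228 with an estimated correlation), the matrix genes Thbs1 by 6.53 ± 0.83 and Thbs2 by 4.79 ± 0.88. Of 41 extracellular matrix genes 13 rose and 1 fell (0.000616, p = 0.0309 with an estimated correlation). Of 22 formative genes 8 rose and 1 fell (0.000295, p = 0.129 with an estimated correlation), Zic2 by 2.11 ± 0.26. Of 30 DNA replication genes 4 fell (0.0181, p = 0.163 with an estimated correlation; 0.0636 without WT 1). Without Ago1_2 KO 1 or Ago1_2 KO 2, 3 and 2 fibroblast, 4 and 2 extracellular matrix and 2 and 2 formative genes rose, and 1 and 1 DNA replication genes fell. Without WT 1, 9 DNA replication genes fell, and without WT 2, 5 formative genes rose. Naive pluripotency genes did not shift as a list in any KO: of 32, 0 rose and 1 fell in Dgcr8 KO, 2 and 3 in Drosha KO and 4 and 2 in Ago1_2 KO (camera adjusted p 0.57, 0.483 and 0.582).

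Cytosolic ribosomal protein genes were lower as a list in each KO, with medians of -0.63, -0.76 and -0.86 over 87 genes in Dgcr8, Drosha and Ago1_2 KO (camera 1.02e-07, 6.58e-11 and 2.77e-12; p = 0.405, 0.329 and 0.303 with an estimated correlation), and 2, 4 and 9 of them fell. Oxidative phosphorylation genes had medians of -0.64, -0.43 and -0.58 over 34 genes (5.31e-07, 0.00015 and 1.43e-06; p = 0.225, 0.332 and 0.238 with an estimated correlation), and 4, 2 and 9 fell. In WT 2 these ribosomal protein genes took 13.4% of counts (95% Wilson interval 13.4% to 13.4%), against 7.80% (7.79% to 7.81%) in WT 1. Fold changes followed transcript length in each KO (Spearman 0.25, 0.24 and 0.3 across 16315 genes). Without WT 2 the ribosomal medians were -0.08, -0.19 and -0.28 and the oxidative phosphorylation medians -0.22, -0.06 and -0.25 in Dgcr8, Drosha and Ago1_2 KO, and the calls of the ribosomal list in Dgcr8 KO (0.329) and the oxidative phosphorylation list in Drosha KO (0.339) ended. Without WT 1, 69, 73 and 78 ribosomal protein genes and 23, 21 and 25 oxidative phosphorylation genes fell in Dgcr8, Drosha and Ago1_2 KO. Without WT 2, 0, 1 and 3 ribosomal protein genes and 1, 0 and 2 oxidative phosphorylation genes fell. Without KO library 1 of each genotype, 0, 0 and 0 of both lists fell, and without KO library 2, 0, 2 and 0 ribosomal protein and 0, 3 and 0 oxidative phosphorylation genes.

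**Figure D2:**
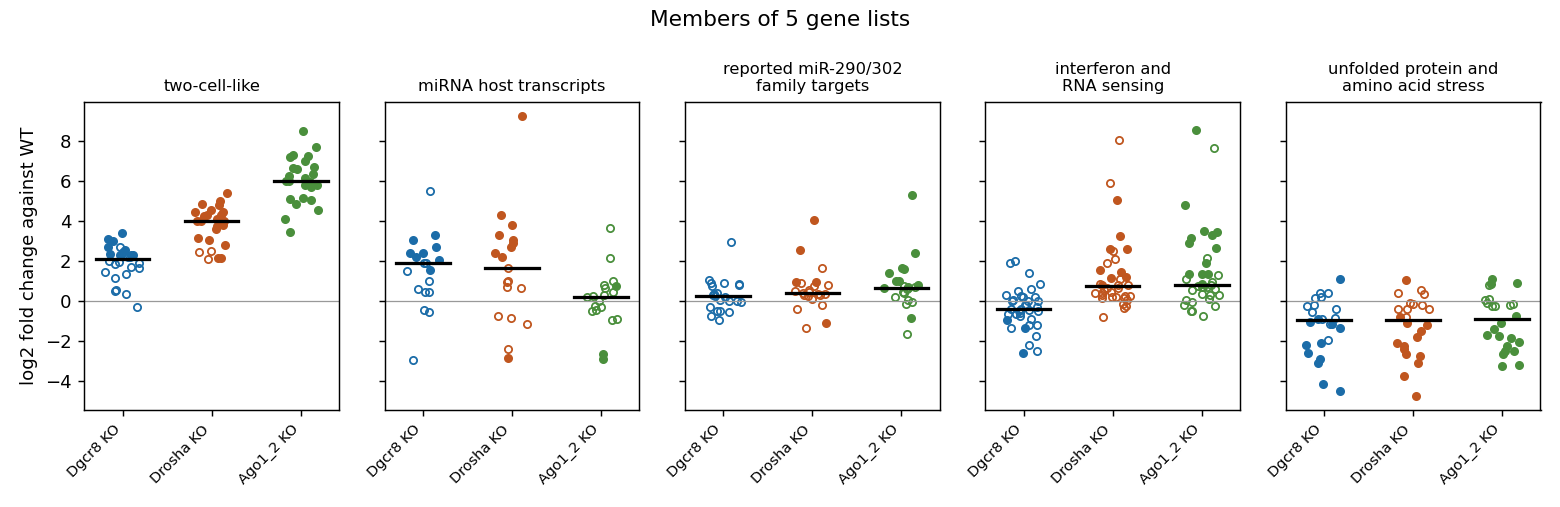
Log2 fold change against WT of the members of 5 gene lists in each KO. Filled points were called, open points were not and lines are medians; the two-cell-like medians were 2.10, 3.99 and 6.02 in Dgcr8, Drosha and Ago1_2 KO.

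Seed sites asked whether mRNAs that miRNAs can bind rose. By t, the miR-290 family seed site GCACTT ranked 1 of all hexamers in Drosha KO (5.41) and 1 in Ago1_2 KO (5.68). Its slopes were 0.1 ± 0.018 and 0.113 ± 0.020 (SE, across 13350 genes, 4403 with the site). Genes are not independent replicates. The hexamer TTGCAC, ranked 2 in Drosha KO, had a slope of 0.102 there (t 5.35). In Dgcr8 KO GCACTT ranked 158, with a slope of 0.037 ± 0.016. The slope of the difference between Drosha KO and Dgcr8 KO was 0.058 ± 0.019, rank 44. The miR-130 family site TGCACT, which shares 5 bases with GCACTT, ranked 67, 3 and 4 in Dgcr8, Drosha and Ago1_2 KO. The 6-base miR-17 family site CACTTT ranked 466, 25 and 102 in these KOs. GCACTT also lies within the 8-base miR-17 family site GCACTTTA, so its rank does not part the miR-290 family from the miR-17 family. Sites of miRNAs of other tissues ranked 843 to 3089 in Dgcr8 KO, 532 to 1432 in Drosha KO and 210 to 1438 in Ago1_2 KO. The let-7 site ranked 2136, 2167 and 2084. Among 2757 genes with a 7-base or 8-base miR-290 family site, camera was called in each KO (2.34e-05, 0.00392 and 0.00135; p = 0.121, 0.212 and 0.183 with an estimated correlation). That test, which unlike the slopes takes no account of UTR length, did not set miRNAs of this cell type apart: of 13 families 12, 11 and 13 were called higher in Dgcr8, Drosha and Ago1_2 KO, and of the 4 families of other tissues 3, 3 and 4. The miR-290 family call ended without WT 2 in Drosha KO (0.515) and Ago1_2 KO (0.223), and without Drosha KO 1 in Drosha KO (0.0584).

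**Figure D3:**
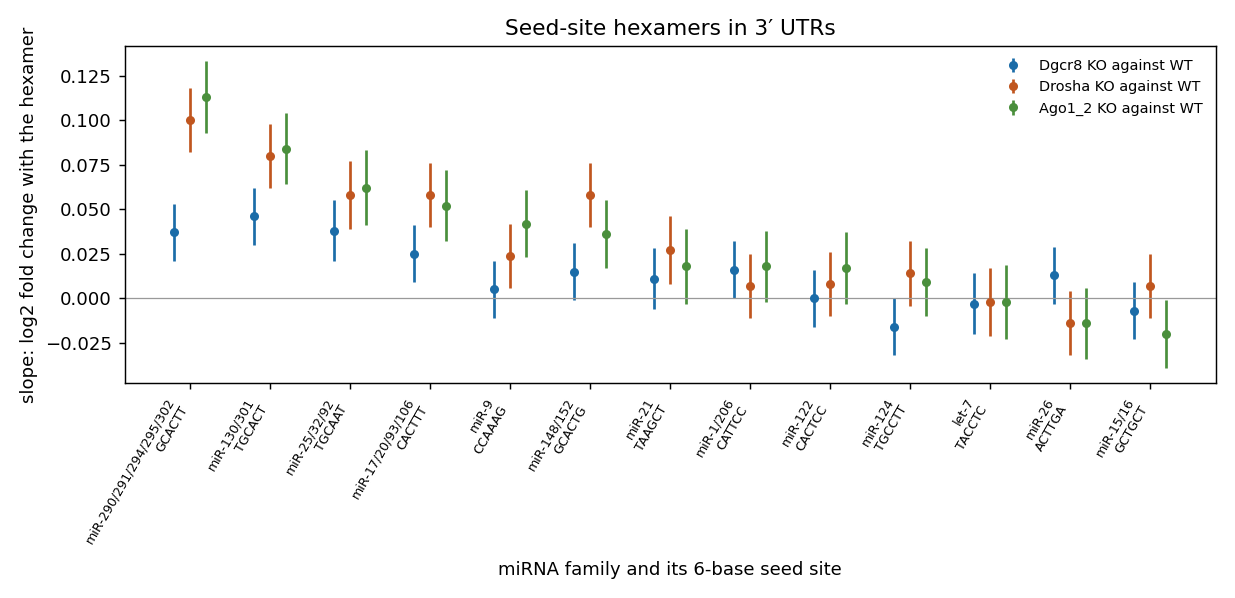
Slope of log2 fold change against WT on the presence of each family's 6-base seed site in the 3′ UTR, with its SE. The miR-290 family site had slopes of 0.037, 0.1 and 0.113 in Dgcr8, Drosha and Ago1_2 KO.

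Genes called in all 3 KOs numbered 120 higher and 115 lower, against 2.68 and 2.62 if the calls were independent. Zscan4b, Rdh1, Inpp4b, Tmem132d, Tmprss3, Pkd1l2, Ror1, BC080695 and Calhm3 were among the largest shared rises, BC080695 and Calhm3 on 0 counts in WT and Rdh1, Inpp4b, Tmem132d and Tmprss3 on 1. P2rx3, Ubap1l, B4galnt2, Ltb, Slc7a11, Chac1, Hapln4, Alox12b, Inhbe and Serp2 had the largest shared falls. Without WT 2 only Rdh1 of these rises kept its call in Dgcr8 KO, and Ltb, Hapln4 and Serp2 of the falls lost theirs. Without WT 1, Tmem132d, Pkd1l2, Ror1, Hapln4 and Alox12b lost theirs in Dgcr8 KO. In Drosha KO, Ror1 and Alox12b lost theirs without WT 1, and Calhm3, Tmprss3, Ror1 and Ltb without WT 2. In Ago1_2 KO, Slc7a11 (-1.67) and Inhbe (-1.85) lost theirs without WT 1, and Tmprss3 without WT 2. Slc7a11 imports cystine and Chac1 degrades glutathione, and both belong to the ATF4 response. Drosha and Ago1_2 KO shared 844 rises, 501 falls and 1 opposite call. Dgcr8 KO shared 169 rises and 142 falls with Drosha KO beside 53 opposite calls, and 169 rises and 180 falls with Ago1_2 KO beside 61. Part of the excess may come from the shared controls. The covariance of fold changes was 0.517 for Dgcr8 and Drosha KO, 0.546 for Dgcr8 and Ago1_2 KO and 1.12 for Drosha and Ago1_2 KO. Simulated unchanged genotypes that share the WT libraries gave 0.102. Their means and spread came from all genotypes, while the WT libraries differed most, by over 2-fold in 2427 genes. The simulated value may therefore understate what the shared WT libraries give. The Pearson correlations of the first 2 pairs, 0.45 and 0.422, were below the simulated 0.499 and 0.493. That of Drosha and Ago1_2 KO, 0.816, was above the simulated 0.501. Sharing controls fixes the simulated correlations, so lying below them does not measure how alike the KOs were. The shared response of 235 genes was 10 without Dgcr8 KO 1, 15 without Dgcr8 KO 2, 496 without Drosha KO 2, 63 without Ago1_2 KO 1, 61 without Ago1_2 KO 2, 1727 without WT 1 and 120 without WT 2.

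Drosha KO was set against Dgcr8 KO to ask whether the partners' losses act alike, with dispersions fitted over all 8 libraries, WT included. Lin28a was lower in Drosha KO by a log2 change of -6.92 ± 0.54 (SE, 2 libraries per group, edgeR adjusted p 0.000278), Htr5a by -6.82 ± 0.47 and T by -8.36 ± 0.74. Plagl1 was lower by -5.98 ± 0.27, while Tpm2 (3.58 ± 0.40) and Stmn3 (4.01 ± 0.38) were higher. The Y-linked genes were higher, Ddx3y at least 1150-fold, Eif2s3y at least 865-fold, Uty at least 439-fold, Zfy1 at least 265-fold and Uba1y 3100-fold (95% interval 555 to 122000), though Zfy1 had 35.1 and 10.8 CPM and Uba1y 159 and 41.9 CPM in Drosha KO 1 and Drosha KO 2. Nat8f3 was 384-fold lower (68.5 to 15200) and Nat8f7 at least 89.8-fold lower. In all 2525 genes were called, 1585 higher and 940 lower. The count was 320 without Dgcr8 KO 1, 341 without Dgcr8 KO 2, 3900 without WT 1, 3866 without WT 2, 1590 without Ago1_2 KO 1 and 1586 without Ago1_2 KO 2. The 10 genes with the largest changes kept their call without each library. Of the 3 with over 3 counts in both groups, the fold moved by over 1.5-fold for 2 without Drosha KO 1 and 3 without Drosha KO 2.

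In the same comparison 11 of 36 lists were called, 8 higher and 3 lower, and none held after adjustment with an estimated correlation. Fold changes here followed transcript GC content (Spearman 0.43). With the GC offset 1944 genes were called, 1619 of them among the 2525. List tests were not repeated with the offset here, so a part of the GC trend in these list calls is not excluded. Of 36 interferon genes 15 were higher in Drosha KO (18 adjusted over the list alone; camera 1.18e-07, p = 0.0527 with an estimated correlation), among them Ifitm1, Oas3, Oasl1 and Xaf1. Of 26 two-cell-like genes 15 were higher (23 adjusted over the list alone; 1.67e-08, p = 0.141 with an estimated correlation). Of 20 Wnt targets 11 were lower (5.44e-05, p = 0.0333 with an estimated correlation), of 15 neuroectoderm genes 8 higher (0.00116, p = 0.0158 with an estimated correlation) and of 24 glycolysis genes 6 higher (0.00116, p = 0.122 with an estimated correlation). Without Dgcr8 KO 1 or Dgcr8 KO 2, 2 and 2 interferon genes, 0 and 2 two-cell-like genes and 2 and 1 neuroectoderm and 2 and 2 glycolysis genes were higher and 4 and 3 Wnt targets lower. Without Drosha KO 1, 5 two-cell-like genes were higher, and without Drosha KO 2, 3 glycolysis genes higher and 7 Wnt targets lower. Of 41 extracellular matrix genes 11 were higher and 1 lower (0.000149, p = 0.0211 with an estimated correlation), of 24 cholesterol synthesis genes 6 higher (0.00472, p = 0.0425 with an estimated correlation) and of 15 trophectoderm genes 6 higher and 3 lower (0.0306, p = 0.117 with an estimated correlation). Of 27 lysosome genes 3 were higher (0.0239, p = 0.457 with an estimated correlation), of 39 germline genes 3 higher and 7 lower (0.00895, p = 0.187 with an estimated correlation) and of 30 DNA replication genes 2 lower (0.00847, p = 0.126 with an estimated correlation). Without Dgcr8 KO 1 or Dgcr8 KO 2, 6 and 6 matrix, 1 and 1 cholesterol, 0 and 1 trophectoderm and 0 and 0 lysosome genes were higher and 2 and 2 germline and 0 and 0 DNA replication genes lower. Without Drosha KO 1, 9 lysosome genes were higher, and without Drosha KO 2, 0 lysosome genes were higher and 0 DNA replication genes lower. Stress genes did not separate these KOs, with 1 of 24 lower and a median of -0.03 (0.625).

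**Figure D4:**
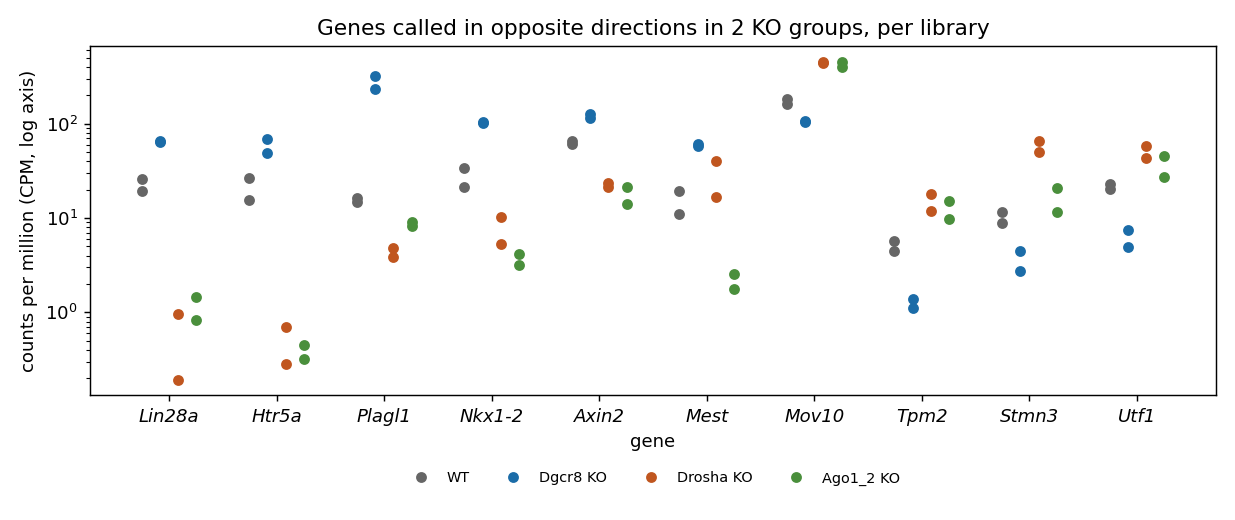
CPM on a log axis of 10 genes called in opposite directions in Dgcr8 KO and another KO, with 1 point per library. Lin28a averaged 22.8 in WT, 65.2 in Dgcr8 KO, 0.579 in Drosha KO and 1.15 in Ago1_2 KO.

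Ago1_2 KO was set against the mean of Dgcr8 and Drosha KO to part loss of the effector from loss of processing. The 2 groups averaged differed from each other in 2525 genes, which their mean hides. Against WT, Wnt targets were called higher in Dgcr8 KO and lower in Drosha KO. Interferon genes were called higher in Drosha KO and were not called in Dgcr8 KO. Calls of such lists here do not part the effector from processing. Primary miRNA genes were lower in Ago1_2 KO: Mir27b by -5.18 ± 0.50, Mir24-1 by -4.99 ± 0.45 and Mir19b-1 by -4.47 ± 0.56 (SE, edgeR adjusted p 0.000834, 0.000695 and 0.0023). Of 166 annotated miRNA genes 33 were lower and 1 higher (40 and 2 adjusted over the list alone), the 1 camera call of this comparison that held after adjustment with an estimated correlation (5.38e-10, p = 0.00077 with an estimated correlation). Of 19 host transcripts 9 were lower (5e-08, p = 0.00723 with an estimated correlation). The 26 two-cell-like genes were all higher, by a median of 3.18 (7.84e-30, p = 0.0264 with an estimated correlation). Ctcfl, Krt17, D13Ertd608e, Zscan4b and Thbs1 had the largest rises, and Ctcfl was high in 1 Ago1_2 KO library, at 24.3 CPM against 1.05. Kis2 and the imprinted gene Mest were lower by -4.65 ± 0.45 and -4.28 ± 0.45. In all 1050 genes were called, 874 higher and 176 lower. The count was 127 without Ago1_2 KO 2, 308 without Ago1_2 KO 1, 320 without Dgcr8 KO 1, 340 without Dgcr8 KO 2, 1589 without WT 1 and 1585 without WT 2. Of the 10 largest changes, 9 kept their call without Ago1_2 KO 1, Ago1_2 KO 2, Dgcr8 KO 1 or Dgcr8 KO 2.

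In the same comparison, where fold changes followed transcript GC content (Spearman 0.25), 13 of 36 lists were called, 8 higher and 5 lower. These list tests were not repeated with the GC offset. Only 1 held after adjustment with an estimated correlation, where 7 had an unadjusted p under 0.05. Of 15 neuroectoderm genes 7 were higher in Ago1_2 KO (camera 1.44e-05, p = 0.00747 with an estimated correlation), led by Pax6 (3.89 ± 0.36), of 12 fibroblast genes 4 (3.83e-06, p = 0.00615 with an estimated correlation) and of 36 interferon genes 10 (5e-08, p = 0.0519 with an estimated correlation). Of 41 extracellular matrix genes 5 were higher (9.58e-06, p = 0.0148 with an estimated correlation), of 24 cholesterol synthesis genes 3 (0.000271, p = 0.0236 with an estimated correlation), of 21 Nodal, TGF-beta and BMP targets 5 (0.00106, p = 0.117 with an estimated correlation) and of 22 miR-290 family targets 3 (0.0047, p = 0.114 with an estimated correlation). Of 20 Wnt targets 5 were lower and 1 higher (0.0104, p = 0.112 with an estimated correlation). DNA replication genes (1 higher of 30; 0.0047, p = 0.119 with an estimated correlation) and ribosomal protein genes (0 of 87; 0.0165, p = 0.683 with an estimated correlation) were lower as lists. Without Ago1_2 KO 1 or Ago1_2 KO 2, 14 and 12 annotated miRNA genes were lower and 23 and 14 two-cell-like, 2 and 1 neuroectoderm, 2 and 1 fibroblast, 1 and 0 interferon and 3 and 0 matrix genes higher. Without Dgcr8 KO 1 or Dgcr8 KO 2, 4 and 3 neuroectoderm, 1 and 3 fibroblast, 1 and 2 interferon and 1 and 1 matrix genes were higher. Without Ago1_2 KO 1, Ago1_2 KO 2, Dgcr8 KO 1 and Dgcr8 KO 2 in turn, 1, 0, 1 and 3 Nodal, TGF-beta and BMP targets, 1, 0, 1 and 1 miR-290 family targets and 0, 0, 0 and 0 cholesterol genes were higher, and 1, 1, 2 and 2 Wnt targets lower. Without Ago1_2 KO 2, 5 host transcripts were lower, and without Drosha KO 1, 8 matrix genes were higher and 3 Wnt targets lower.

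Chromosome medians checked for gain or loss of chromosomes, which occurs in cultured stem cells. In Dgcr8 KO the median log2 fold change of 613 genes on chromosome 15 lay -0.385 from that of all genes and of 789 genes on chromosome 17 lay -0.327 from it, both at percentile 0 of random gene sets. Chromosome 7 was also at percentile 0 (-0.112), and chromosomes 3, 13, 18 and X were at percentile 100, at 0.153, 0.212, 0.237 and 0.265. With the GC offset, chosen after the data were seen, chromosomes 1, 15 and 17 lay at -0.198, -0.269 and -0.149, each at percentile 0, chromosome 18 at 0.157 (percentile 100), and chromosomes 3, 7, 13 and X at 0.01, 0.038, 0.069 and 0.104. Chromosome 15 lay 0.108 and 0.174 above all genes in Drosha and Ago1_2 KO. Chromosome 1 lay at -0.086, -0.171 and -0.158 in Dgcr8, Drosha and Ago1_2 KO, which share the WT libraries.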

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

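All tests of explanations in this part were chosen after the results were seen. Genes called in opposite directions against WT, with a tested difference between the KO groups, were singled out. In Drosha KO against Dgcr8 KO the log2 difference was -6.92 for Lin28a, -6.82 for Htr5a, -5.98 for Plagl1, -3.74 for Nkx1-2 and -2.44 for Axin2, and 4.01 for Stmn3, 3.58 for Tpm2, 3.02 for Utf1, 2.83 for Anxa2 and 2.09 for Mov10. Ddx3y was at least 1150-fold, Uty at least 439-fold, Zfy1 at least 265-fold and Mir1306 at least 111-fold higher in Drosha KO, and Uba1y 3100-fold higher on 1 count in Dgcr8 KO. In Ago1_2 KO against Dgcr8 KO the log2 difference was -4.82 for Mest, 5.47 for Rhox9, 2.23 for Hk1 and 1.71 for Psap, and Mir20b was at least 30-fold lower.

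The 4 of 7 listed Y-linked genes that passed the low-count filter, all on the Y short arm, had no counts in both libraries labelled Dgcr8 KO. Low depth is argued against, since at the lower WT level the smallest expected count over the 4 genes and both libraries was 38.8. Against a line with both X chromosomes active stands only a bound of 0.5, chosen after the values were seen. X-linked genes lay 0.265 above all genes (95% bootstrap interval 0.184 to 0.343), and 0.104 above with the GC offset, both under that bound. The interval is drawn over genes and does not measure the spread between cultures. The other 6 genes of the Y short arm with 20 counts or more elsewhere had 0 or 1 count in the Dgcr8 KO libraries. An absence of the short arm would give such counts. Annotated genes of chromosome Y together held 1830 and 1602 counts in these libraries, not scaled to library size. They held 4606 and 6438 counts in WT and 5993 to 11196 in the other KO libraries. Whether the rest of the chromosome was absent, and whether these cells lost the arm in culture or came from another line, stays open, and other sources could give the same counts.

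The list of unfolded protein and amino acid stress genes was lower in all 3 KO groups, although not all of its members fell. One WT library alone is argued against, since without either WT library the highest of the 3 list medians was -0.80. A GC trend is argued against as the whole cause, since after the GC offset the highest median was -0.69. A state of the WT cultures shared by the 3 comparisons and an effect of the mutations cannot be told apart, because the same WT libraries enter each comparison; the list median of Drosha KO against Dgcr8 KO was -0.03.

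Two-cell-like genes were higher in Ago1_2 KO and Drosha KO. Reads shared between near-identical copies are argued against as the whole cause: the 4 members with 90% or more of their 50-base windows found in no other annotated gene had medians of 3.70 in Drosha KO and 5.19 in Ago1_2 KO, and all 4 were called in both. A single library is argued against, since the smallest median with 1 library left out was 3.63. Ago1_2 KO lay 3.18 above the mean of the others, so these genes did not stand at equal levels in the 3 mutants. Whether miRNA loss itself acted equally in the mutants is not decided by this, since genotype and culture cannot be told apart. Effects of clone, passage or culture may still account for the order of the genotypes and were not tested.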

How the results depend on the processing

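Of the alternatives, the GC offset was chosen after seeing the data, and the others before the data were examined; those for values that are not counts were not run. Scaling with DESeq2 size factors, library size only, limma-voom, a filter of 1 CPM and a 2-fold limit kept every count of called genes within 1.5 times its value. Without a low-count filter the counts were 3241, 3413 and 4431 for Dgcr8, Drosha and Ago1_2 KO, 1939 for Ago1_2 KO against the mean of the others and 869 for the shared response. With only the groups compared they were 723, 589, 1595 and 98 for Dgcr8 KO, Drosha KO, Ago1_2 KO against the mean and the shared response. DESeq2 with its default filtering, given 27381 genes against 16388, so that test and filter changed together, gave 2335 for Dgcr8 KO and 528 for the shared response, and the GC offset gave 722 for Dgcr8 KO. The GC offset ended 1 list call of the comparisons with WT, that of lysosome and autophagy genes in Dgcr8 KO (adjusted p 0.0932). It changed the sign of 1 called gene in Dgcr8 KO, which the report does not name. Of its 722 calls there, 600 were shared with the main test. It added list calls in Dgcr8 KO (camera adjusted p). Mitochondrially encoded mRNAs (0.00183) and cholesterol synthesis (0.0185) were lower, and mesoderm (0.0217) and let-7 target lists (0.0483) higher. Cholesterol synthesis was added as higher in Ago1_2 KO (0.048). Leaving out libraries gave 40 to 4245 for Dgcr8 KO, 714 to 4003 for Drosha KO, 556 to 4955 for Ago1_2 KO, 320 to 3900 for Drosha KO against Dgcr8 KO, 127 to 1589 for Ago1_2 KO against the mean and 10 to 1727 for the shared response; a lone library was assumed to vary like the other groups. The cause was not tested. Of 13, 14 and 12 lists called in Dgcr8, Drosha and Ago1_2 KO, 0, 1 and 0 held with an estimated correlation, and 5, 9 and 7 with fry, which called 8 lists in Dgcr8 KO. Ago2 in Ago1_2 KO was called without the filter (-0.75) and without WT 2 (-1.15), and lay between -1.15 and -0.11 over the left-out libraries. Ago2 in Dgcr8 KO lay between -0.01 and 1.03 and Drosha mRNA in Dgcr8 KO between -0.1 and 0.05. The miR-290 family site difference lay between 0.174 and 0.452, 0.111 and 0.366, and 0.161 and 0.418 in Dgcr8, Drosha and Ago1_2 KO, and its call was lost without WT 2 in the last 2. List tests of the comparisons among KOs were not repeated with libraries left out. Among named values those that reversed, none of them called, were Drosha mRNA in Dgcr8 KO with library size only (0.06), with the GC offset (0.11), without Dgcr8 KO 1 (0.05) and without WT 1 (0.03), and Ago2 in Dgcr8 KO without WT 2 (-0.01).

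The replicate block, with the replicate number as a term, gave 2795, 2884 and 4053 called genes in Dgcr8, Drosha and Ago1_2 KO and 650 for the shared response. It kept the list calls of the comparisons with WT. It added the miRNA machinery in Drosha KO (camera adjusted p 0.0439) and cholesterol synthesis in Ago1_2 KO (0.0368), both higher. The labels do not say that equal numbers were handled together. Residuals of libraries with the same number correlated at 0.096 to 0.24 between genotypes, all positive. The trend of log2 CPM with GC, at 60% minus 40%, was higher in library 2 of each genotype. It was -0.81 and -0.64 in Dgcr8 KO and 0.072 and 0.46 in Drosha KO. In Ago1_2 KO it was -0.024 and 0.43, and in WT -0.08 and 0.6. The ribosomal protein share of counts was also higher in each library 2. A batch by replicate number is not excluded, and the main test takes no account of it.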

Other observations

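Some imprinted genes, chosen after their values were seen, stood at different levels in the mutants, while the list of 38 was not called in Drosha KO against Dgcr8 KO (camera adjusted p 0.094) or in Ago1_2 KO against the mean of the others (0.157). Plagl1 stood at 276 CPM in the libraries labelled Dgcr8 KO, 15.5 in WT, 4.33 in Drosha KO and 8.75 in Ago1_2 KO. Peg10 was higher than WT in each KO, at 159, 50 and 32 CPM in Dgcr8, Drosha and Ago1_2 KO against 8.59. Mest stood at 59.5 CPM in Dgcr8 KO and 2.15 in Ago1_2 KO, against 15.1 in WT. No test of explanations was run for these genes.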
